A study of Mus musculus with 6 samples.

How the data were processed

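RNA was measured in whole livers of C57BL/6 mice, collected 24 h after an intraperitoneal dose of 300 mg/kg acetaminophen given to fasted animals, per the labels' protocols. The 6 libraries fall into 2 groups of 3: Flox mice and HepKO mice, whose genotype labels name no gene. The series title names NEDD4-1 as the ubiquitin ligase under study, so Nedd4 was taken as the targeted gene. Poly(A) RNA was selected, fragmented and copied with a second strand marked by dUTP, and sequenced as paired reads, per the labels' protocols. Whether the quantification used strand is not given in the sources used here. The series design gives n = 3 per group, and the labels do not say that each library is 1 animal, so p-values measure the spread between these libraries.

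The deposited table holds 28476 genes with the FPKM of each library, which the authors computed from the reads; the unit comes from the file headers. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, DESeq2 and edgeR without saying what each was used for. The deposited p-value and q-value columns are the authors' own, and the tool behind them is not given in the sources used here. The deposited log2 fold change of the authors equals the log2 ratio of the mean FPKM of HepKO to that of Flox for 21510 of the 21511 genes with a finite value, within 0.001. The authors' p-value is exactly 1 for 14693 genes. Over the other 13783 genes, the deposited q-value lies within 0.00239 of a Benjamini-Hochberg adjustment.

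The genome build is not given in the sources used here. Of the gene identifiers, 28396 are in GENCODE M21 on GRCm38, and 25619 of those have the same chromosome, start and end there, so coordinates are given as GRCm38. A value of 0 in every library was found for 2003 genes, and 49 symbols belong to more than 1 identifier.

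FPKM are not counts, so no count test was run, and the count-based alternatives did not apply. Depth per library is unknown. The most frequent log2 ratios of low FPKM values between library pairs lay between -0.31 and 0.23, and the modal bins held only 3.60% to 5.17% of those genes, so relative depths are rough.

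Genes with a mean of at least 0.5 FPKM over the 6 libraries (12712) were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with genotype as the only term and the variance trend, two-sided. Adjustment was by Benjamini-Hochberg with a threshold of 0.05. Log2 fold changes are on this scale, which understates the change of genes with low FPKM; folds are ratios of group mean FPKM. Nedd4 and Vdac1 were also tested with an exact two-sided permutation test of the group means (scipy 1.17.1), for which 3 against 3 libraries cannot go below p = 0.10. Summaries and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

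Of 52 gene lists fixed before the data were examined, 48 had at least 5 tested members and were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 48 lists. Of the 1184 list entries, in which a gene can appear more than once, 1167 were matched to the table, 8 of them through an older symbol. The lists were also tested with the correlation estimated per list and with fry. The p-value of fry tests whether a list's genes move, on balance, one way, and does not compare them with other genes.

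The genes named follow a rule also set before the data were examined: Nedd4 and Vdac1; the 8 largest rises and 8 largest falls among genes past the threshold with a proper symbol, a mean of at least 1 FPKM and no overlap between groups; up to 4 members in the direction of each of the 10 called lists with the smallest p; and the 2 most abundant members of 8 lists tied to the design. The members taken from called lists were those with the largest changes among members with no overlap between groups. Genes named beyond this rule were chosen after their values were seen. Of the genes the rule names, 2 are not reported here.

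Alternatives were other pseudocounts, filters, rescalings, limma settings, thresholds, a replicate block and leaving out each library in turn. For the gene lists, Nedd4, Vdac1 and the named genes, 2 rescalings to a common sum were added after seeing the data. The test was run on simulated data with 200 changed genes among the 12712. It recovered 2 of 67 genes changed 1.5-fold (2.99%), 24 of 67 changed 2-fold (35.8%) and 50 of 66 changed 4-fold (75.8%), called 3 unchanged genes and gave 0 calls in the wrong direction. The real data called 2583 genes, far more than were changed in the simulation. The adjustment is stricter where fewer genes change, so these shares do not give the recovery in the real data. The recovery first required of 4-fold changes was not reached, and that requirement was lowered after the value was seen.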

Results

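The transcriptomes of 6 mouse livers were compared 24 h after 300 mg/kg acetaminophen (APAP), a drug whose overdose damages hepatocytes: 3 from Flox mice and 3 from HepKO mice. The question, from the series title, was how loss of the ubiquitin ligase NEDD4-1 bears on the injury and on VDAC1. Livers without acetaminophen are not analysed here, so differences are between treated genotypes. Each library summed to between 456176 and 496303 FPKM, with 10402 to 10763 genes at 1 FPKM or more. Depth is unknown. HepKO replicate 1 stood apart in its mitochondrial share, 24.6% of its FPKM against 17.2% and 18.3% in the other HepKO livers and 16.7% to 18.1% in the Flox livers.

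Nedd4, which encodes the targeted HECT-type ubiquitin ligase (ENSMUSG00000032216, chromosome 9, 72662346 to 72749852), was lower in every HepKO liver. Its level was 2.18, 2.59 and 2.23 FPKM in the Flox livers and 0.618, 0.666 and 0.565 FPKM in the HepKO livers, a 3.78-fold difference of means (log2 fold change -1.04, SE 0.10, limma adjusted p = 0.0015). Vdac1, which encodes a channel of the outer mitochondrial membrane (ENSMUSG00000020402, chromosome 11, 52360860 to 52389397), had 60.0 ± 3.45 FPKM in Flox and 53.6 ± 6.04 FPKM in HepKO livers (SD, n = 3). Its log2 fold change of -0.16 had a 95% limma interval of -0.44 to 0.12 and did not pass (adjusted p = 0.36); it was -0.073 without HepKO replicate 1 and -0.23 without HepKO replicate 2. Exact two-sided permutation tests gave p = 0.10 for Nedd4, the smallest possible with 3 against 3, and p = 0.20 for Vdac1. Whole liver includes cells other than hepatocytes, and these are transcript levels, not protein.

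**Figure D1:**
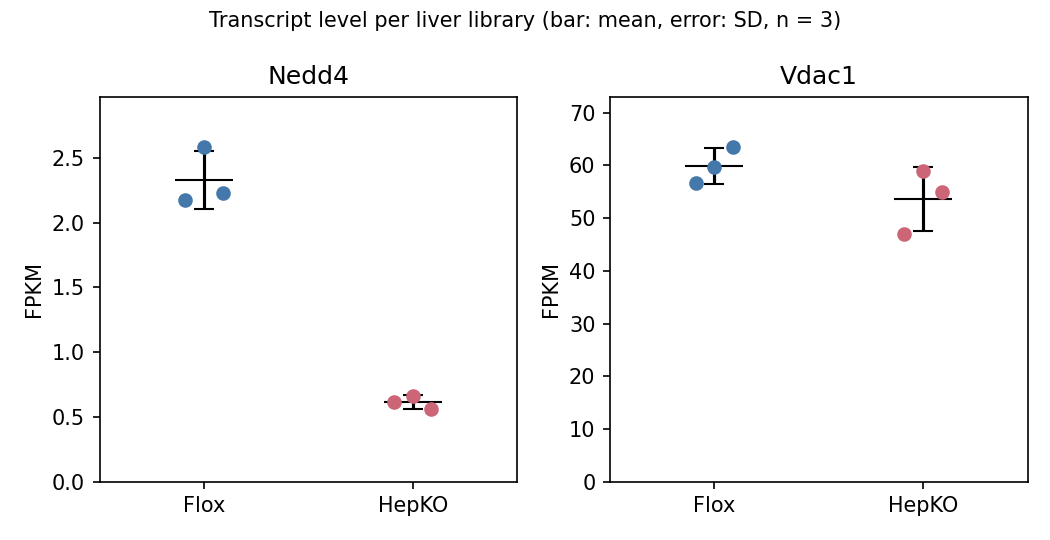
FPKM of Nedd4 (left) and Vdac1 (right) in each liver library, Flox and HepKO, with the mean and SD of 3. The Nedd4 points of HepKO livers, 0.565 to 0.666 FPKM, lie below all Flox points, and the Vdac1 points overlap.

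Of the 9 tested NEDD4 family members, 3 fell and 6 did not pass; adjusted over the list alone, 3 fell and 1 rose. Besides Nedd4, the ligase Wwp1 fell from 10.3 to 6.05 FPKM and the adaptor Ndfip1 from 15.6 to 9.77 FPKM. Both calls were lost without Flox replicate 2 (adjusted p = 0.051 for each) or HepKO replicate 2 (0.052 for Wwp1, 0.063 for Ndfip1), and that of Ndfip1 also without Flox replicate 3 (0.055). The list did not pass (camera adjusted p = 0.75). Its median log2 fold change was 0.08, and 0.0095 at its lowest without 1 library, and its mean was -0.15. With fry the list had adjusted p = 0.021 downward, but it includes the targeted Nedd4 itself and was not tested without it. Among 14 genes of voltage-dependent anion channels and the permeability transition, 3 rose (Hk1, Hk2 and Mcl1) and 1 fell (Vdac3); adjusted over the list alone, 3 rose and 2 fell. That list did not pass either (adjusted p = 0.75; median -0.03, and -0.15 to 0.05 without 1 library; mean 0.07). Its most abundant members besides Vdac1 were Slc25a5, a mitochondrial nucleotide carrier, with 365 FPKM in Flox and 313 FPKM in HepKO livers (adjusted p = 0.31), and Mcl1, an antiapoptotic BCL2-family gene, which rose from 51.5 to 84.3 FPKM. The Mcl1 call was lost without Flox replicate 2 (adjusted p = 0.072), Flox replicate 3 (0.051) or HepKO replicate 2 (0.062). Hk1, Hk2 and Vdac3 were chosen after their values were seen.

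The lists of immediate early, hypoxia, neutrophil and extracellular matrix genes were called as higher in HepKO livers, and those of complement and coagulation, bile acid handling and amino acid breakdown as lower. These calls were made at the preset correlation of 0.01; with an estimated correlation no list passed, the smallest adjusted p being 0.073. Fos, a transcription factor gene of the immediate early class, rose 30.3-fold, from 2.63 ± 0.70 to 79.8 ± 3.10 FPKM (SD, n = 3). Cyp2a5, a cytochrome P450 gene, fell 20.3-fold, from 249 ± 104 to 12.3 ± 1.39 FPKM, and Slco1b2, a hepatocyte uptake transporter gene, fell 7.55-fold, from 63.2 ± 5.77 to 8.37 ± 0.61 FPKM. In all, 2583 of 12712 genes passed, 1186 higher and 1397 lower in HepKO livers (limma, adjusted p 0.05). Of these 2583, 432 were higher and 264 lower by at least 1 on the log2 scale. The balance depended on the scaling: 1434 were higher and 1137 lower after median-ratio rescaling, and 1350 higher and 1231 lower after rescaling to a common sum without the 50 most abundant and the mitochondrial genes, but 1093 higher and 1417 lower after rescaling to a common sum of all genes. The last of these also tested more genes (14824) and gave the pseudocount less weight. The total was 1322 without Flox replicate 2, 1480 without Flox replicate 3, 1306 without HepKO replicate 2, and 1661 (869 higher, 792 lower) without HepKO replicate 1; 1086 of the genes were called in all 6 such fits.

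Other large rises were those of Igfbp1 (10.9-fold, to 842 FPKM, and 22.3-fold without Flox replicate 1), a hepatic secreted binding protein of insulin-like growth factors, the chemokine Cxcl10 (18.2-fold), the antiproliferative Btg2 (14.5-fold), the stress gene Gadd45a (16.5-fold), Ier3 (15.1-fold) and the lipid-droplet gene Hilpda (11.8-fold, and 17.99-fold without Flox replicate 1). Among the largest falls, the aldo-keto reductases Akr1c6, Akr1c20 and Akr1c14 fell 14.0-fold, 13.7-fold and 6.45-fold. The carboxylesterases Ces1g and Ces1d fell 8.12-fold and 6.28-fold, and Akr1d1, a steroid reductase of bile acid synthesis, fell 8.31-fold. All of these passed at adjusted p = 0.0066 or less. Members of the Akr1c, Ces1 and Cyp2a clusters have near-identical copies, so their single-gene levels are uncertain. So are those of Akr1d1, Dusp1, Ankrd37, Serpind1 and Mcm7, which overlap other expressed genes.

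**Figure D2:**
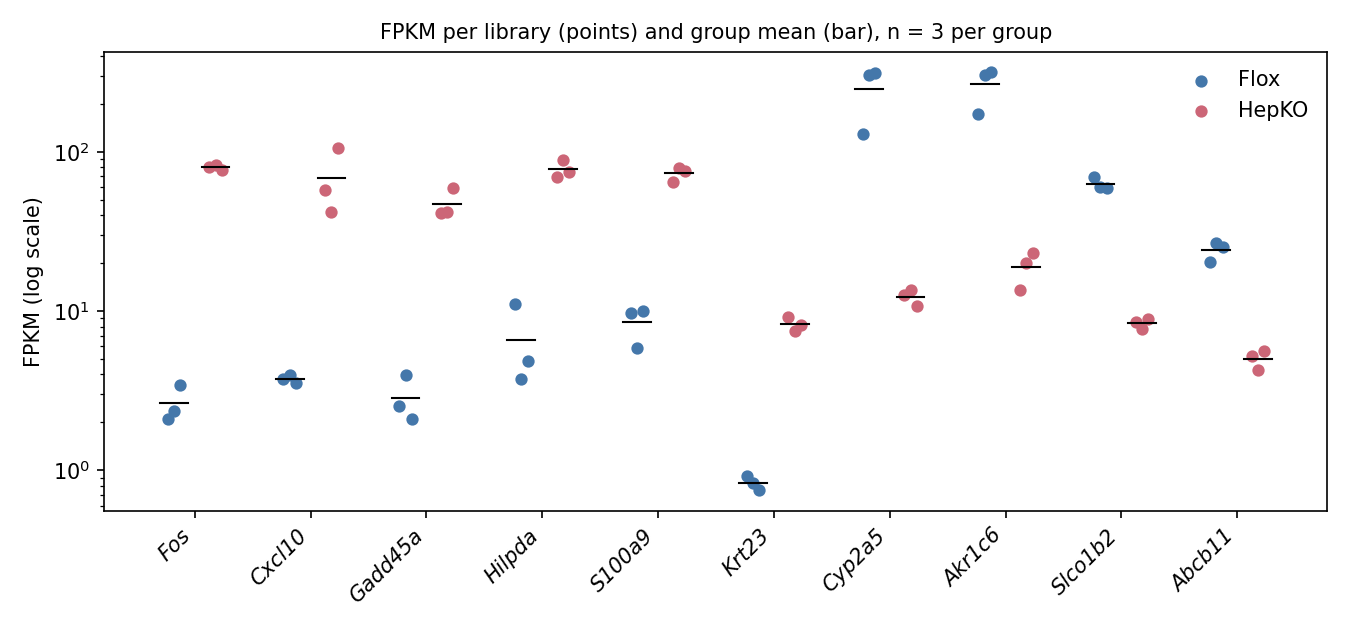
FPKM on a log axis for 10 named genes, each point 1 library and each bar the mean of 3. The Flox and HepKO points of each gene do not overlap, since the rule that named these genes required it. Of all tested genes, 42.4% have groups that do not overlap. Fos, for example, has means of 2.63 and 79.8 FPKM.

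Gene lists fixed in advance were called in 31 of 48 cases with the preset correlation, 17 upward and 14 downward. With the correlation estimated per list, camera called 0 of 48, the smallest adjusted p being 0.073, and 9 lists had an unadjusted p under 0.05; fry called 31, of which 26 were shared. Called lists that did not pass with fry were nuclear oxidative phosphorylation and dendritic cell genes (adjusted p = 0.071 each), Kupffer cell markers (0.20), mitochondrial genome transcripts (0.44) and ribosomal proteins (0.65). Lists that passed only with fry were glycolysis and gluconeogenesis (adjusted p = 0.014, upward) and, downward, the insulin, IGF and growth hormone axis (0.014), lipogenesis (0.021), the NEDD4 family (0.021) and autophagy and mitophagy (0.027). The NEDD4 family list includes the targeted Nedd4 itself.

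Immediate early genes formed the most distinct group. Of 23 tested members of the MAPK and immediate early list, 20 rose, 0 fell and 3 did not pass; adjusted over the list alone, 21 rose and 1 fell. The median log2 fold change was 1.87 (camera adjusted p = 3.17e-19; adjusted p = 0.073 with an estimated correlation). Besides Fos, Gadd45a and Ier3, the phosphatase gene Dusp1 rose 8.96-fold. Of 14 hypoxia and angiogenic genes, 11 rose (13 adjusted over the list alone), among them the vasodilator peptide gene Adm (7.83-fold), the glucose transporter Slc2a1 (6.66-fold), Ndrg1 (6.01-fold) and Ankrd37 (13.5-fold); the list had adjusted p = 2.88e-11, and adjusted p = 0.14 with an estimated correlation. Of 16 p53 targets, 7 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.0018, and adjusted p = 0.15 with an estimated correlation). Of 23 unfolded protein response genes, 7 rose and 0 fell (9 and 0 adjusted over the list alone; adjusted p = 0.0023, and adjusted p = 0.33 with an estimated correlation). Cytosolic heat shock genes split, 3 higher and 3 lower of 16 (3 and 4 adjusted over the list alone), and the list did not pass (adjusted p = 0.51).

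Matrix and progenitor lists were called as higher. Of 29 extracellular matrix and fibrogenesis genes, 16 rose and 0 fell (17 and 1 adjusted over the list alone), among them the matricellular genes Ccn1 (9.73-fold), Thbs1 (8.08-fold) and Ccn2 (4.81-fold); the list had adjusted p = 3.37e-08, and adjusted p = 0.26 with an estimated correlation. YAP and Hippo targets, which share Ccn1 and Ccn2 with that list, had 6 higher and 1 lower of 16 (10 and 1 adjusted over the list alone; adjusted p = 3.58e-05, and adjusted p = 0.14 with an estimated correlation). Of 10 cholangiocyte and progenitor markers, 7 rose and 1 fell, adjusted over the list alone as well, with Krt23 up 9.91-fold, the biliary transcription factor gene Sox9 up 4.31-fold, the keratin Krt18 up 2.98-fold and Cd24a up 5.05-fold; the list had adjusted p = 2.82e-05, and adjusted p = 0.14 with an estimated correlation.

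Neutrophil transcripts rose, at low absolute levels for most. Of 13 tested neutrophil markers, 12 rose and 1 did not pass, adjusted over the list alone as well (median log2 fold change 1.81, adjusted p = 9.34e-11, and adjusted p = 0.15 with an estimated correlation). Retnlg rose from 1.61 to 21.5 FPKM, S100a9 from 8.56 to 73.2, S100a8 from 4.94 to 32.4, and Il1r2 from 0.327 to 6.06. The 2 most abundant members were Lcn2, which rose 3.19-fold from 210.5 to 671 FPKM (4.78-fold without Flox replicate 1), and Wfdc21, which had 589 in Flox and 450.3 in HepKO livers (adjusted p = 0.26). Lcn2 is also in the acute phase list, so its rise need not mark neutrophils. The Lcn2 call was lost without Flox replicate 3 (adjusted p = 0.057), HepKO replicate 1 (0.052) or HepKO replicate 2 (0.058). Of 23 cytokines and chemokines, 15 rose and 1 fell (16 and 1 adjusted over the list alone; adjusted p = 6.33e-09, and adjusted p = 0.24 with an estimated correlation). The neutrophil chemokine Cxcl2 rose 50.7-fold from a level of 0.252 FPKM that leaves the fold uncertain (91.4-fold without Flox replicate 1), Ccl6 4.19-fold and Cxcl13 5.57-fold, the last lost without HepKO replicate 2 (adjusted p = 0.055). Cxcl1 had 48.0 ± 21.3 FPKM in Flox and 80.5 ± 11.3 in HepKO livers (SD, n = 3; limma adjusted p = 0.14).

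Markers of other cell types and related lists were mixed. Monocyte and infiltrating macrophage markers had 7 higher and 1 lower of 20 (10 and 2 adjusted over the list alone; adjusted p = 0.00047, and adjusted p = 0.24 with an estimated correlation). Dendritic cell and MHC class II genes had 2 higher and 0 lower of 7, adjusted over the list alone as well (adjusted p = 0.011, and adjusted p = 0.43 with an estimated correlation). Kupffer cell markers had 2 higher and 1 lower of 14 (3 and 1 adjusted over the list alone; adjusted p = 0.032, and adjusted p = 0.53 with an estimated correlation), a call lost without Flox replicate 2 (adjusted p = 0.055) or HepKO replicate 2 (0.075). Sinusoidal endothelial markers had 4 higher and 1 lower of 20 (6 and 4 adjusted over the list alone; adjusted p = 0.75; median -0.11, mean 0.05), and stellate cell markers 4 higher and 2 lower of 16 (6 and 3 adjusted over the list alone; adjusted p = 0.69; median -0.09, mean 0.02). Erythrocyte transcripts had 4 higher and 0 lower of 6, adjusted over the list alone as well (median log2 fold change 1.87, adjusted p = 0.0080, and adjusted p = 0.31 with an estimated correlation). Acute phase genes had 9 higher and 6 lower of 27 (13 and 6 adjusted over the list alone; adjusted p = 0.017, and adjusted p = 0.49 with an estimated correlation), a call lost without HepKO replicate 1 (adjusted p = 0.052). Interferon-stimulated genes had 2 higher and 4 lower of 27 (2 and 6 adjusted over the list alone) and did not pass (adjusted p = 0.14). The lists for T and NK cells (1 tested member), B and plasma cells (2), muscle and adipose tissue (2) and exocrine pancreas (0) had too few members for a test.

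**Figure D3:**
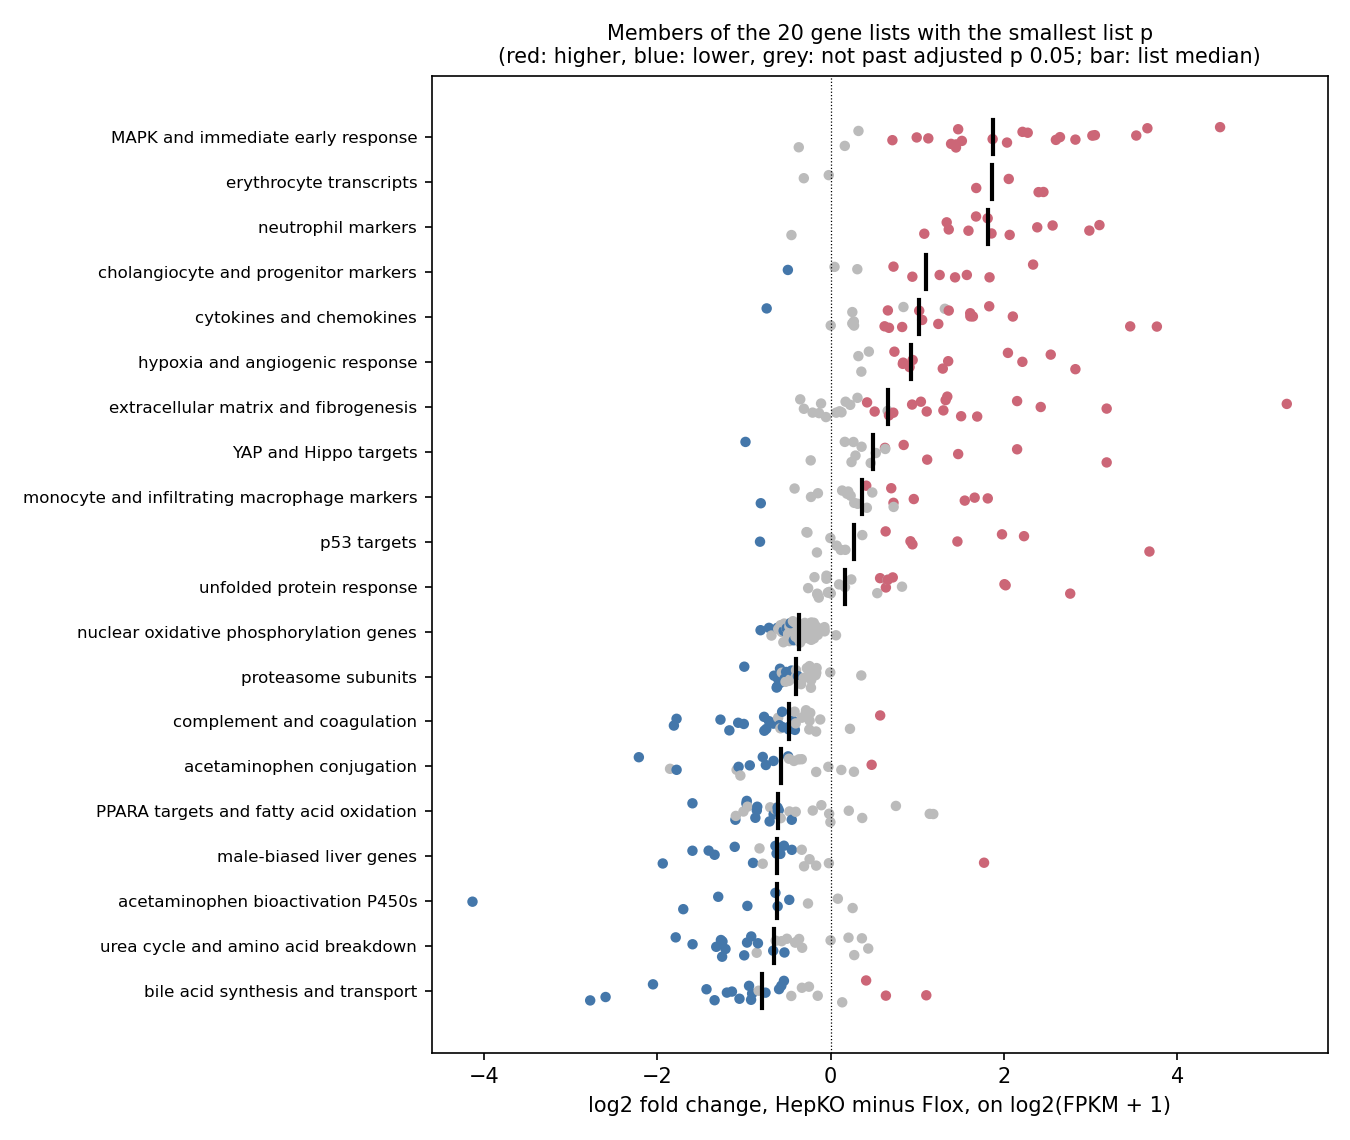
Log2 fold change, HepKO minus Flox on log2(FPKM + 1), of each tested member (points) of the 20 lists with the smallest list p, with the list median (bar); red and blue points passed as higher and lower, grey points did not pass. The immediate early and erythrocyte lists lie farthest to the right, with medians of 1.87 each, and bile acid synthesis and transport farthest to the left, with a median of -0.79.

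Several hepatocyte lists were called as lower. Of 34 complement and coagulation genes, 20 fell and 1 rose (24 and 1 adjusted over the list alone; adjusted p = 3.37e-08, and adjusted p = 0.32 with an estimated correlation), with the kallikrein gene Klkb1 down 4.10-fold, the lectin Mbl1 3.47-fold, Serpind1 2.46-fold and C9 2.31-fold. Of 24 bile acid synthesis and transport genes, 15 fell and 3 rose (16 and 3 adjusted over the list alone; adjusted p = 2.75e-05, and adjusted p = 0.14 with an estimated correlation). Besides Slco1b2 and Akr1d1, the bile salt export pump gene Abcb11 fell 4.78-fold and the uptake transporter Slco1a4 3.61-fold. Of 26 urea cycle and amino acid breakdown genes, 13 fell and 0 rose (16 and 0 adjusted over the list alone; adjusted p = 1.41e-05, and adjusted p = 0.40 with an estimated correlation), among them Hgd (3.56-fold), Haao (2.61-fold) and Uroc1 (2.47-fold). PPARA targets and fatty acid oxidation genes had 13 lower and 0 higher of 31 (18 and 1 adjusted over the list alone; adjusted p = 0.00024, and adjusted p = 0.49 with an estimated correlation).

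Both lists of genes that handle acetaminophen were called as lower at the preset correlation. The bioactivation list holds P450 genes together with Por and Cyb5a. Of its 10 genes, 7 fell and 0 rose, adjusted over the list alone as well (adjusted p = 0.0018, and adjusted p = 0.21 with an estimated correlation). Cyp2e1, the main bioactivating enzyme and the most abundant member, had 915 ± 50.1 FPKM in Flox and 765 ± 79.2 FPKM in HepKO livers and did not pass (SD, n = 3; limma adjusted p = 0.15); Cyp2d9 fell 1.57-fold. Of 20 conjugation genes, 8 fell and 1 rose (12 and 1 adjusted over the list alone; adjusted p = 0.00068, and adjusted p = 0.32 with an estimated correlation). Its 2 most abundant members, the glutathione transferases Gstp1 and Gstm1, did not pass (1315 and 1171 FPKM for Gstp1, 433 and 323 for Gstm1, in Flox and HepKO livers). NRF2 targets and glutathione synthesis genes split, 4 higher and 4 lower of 24, adjusted over the list alone as well (adjusted p = 0.75; median -0.16, mean 0.04). In that list Gsta1 had 337 and 401 FPKM and Srxn1 262 and 174 FPKM in Flox and HepKO livers, and neither passed. Antioxidant enzymes had 3 higher and 3 lower of 20, adjusted over the list alone as well (adjusted p = 0.73; median -0.22, mean 0.01).

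Zonal and sex-biased hepatocyte lists were called as lower too. Several share members with the lists above, so they are not independent of them. Examples are Cyp2e1 (pericentral), Uroc1 (periportal) and Cyp2d9 (male-biased). Pericentral genes had 10 lower and 3 higher of 26 (11 and 3 adjusted over the list alone; adjusted p = 0.012, and adjusted p = 0.44 with an estimated correlation). Periportal genes had 8 lower and 1 higher of 28 (11 and 1 adjusted over the list alone; adjusted p = 0.022, and adjusted p = 0.49 with an estimated correlation), a call lost without Flox replicate 1 (adjusted p = 0.16). Hepatocyte transcription factors had 6 lower and 1 higher of 20 (10 and 1 adjusted over the list alone; adjusted p = 0.011, and adjusted p = 0.40 with an estimated correlation). Male-biased liver genes had 11 lower and 1 higher of 19 (13 and 1 adjusted over the list alone; adjusted p = 0.00024, and adjusted p = 0.23 with an estimated correlation). Female-biased genes had 3 lower and 1 higher of 8 (5 and 1 adjusted over the list alone; adjusted p = 0.049, and adjusted p = 0.31 with an estimated correlation), lost without Flox replicate 1 (adjusted p = 0.070), Flox replicate 2 (0.056), HepKO replicate 2 (0.073) or HepKO replicate 3 (0.077), and after rescaling to a common sum (0.22; median -0.54 against -0.82). That rescaling changed the genes tested and the weight of the pseudocount as well.

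Several other metabolic lists did not pass with camera. Lipogenesis had 4 lower and 0 higher of 21, adjusted over the list alone as well (adjusted p = 0.054), although it passed without Flox replicate 3 (adjusted p = 0.0079) or HepKO replicate 1 (0.045), and after rescaling to a common sum (0.038). Cholesterol synthesis had 1 lower and 0 higher of 24 (0 and 0 adjusted over the list alone; adjusted p = 0.51), glycolysis and gluconeogenesis 8 higher and 5 lower of 27 (9 and 5 adjusted over the list alone; adjusted p = 0.12), and the insulin, IGF and growth hormone axis 4 higher and 4 lower of 17 (4 and 5 adjusted over the list alone; adjusted p = 0.77). Eicosanoid and lipid mediator genes had 2 higher and 3 lower of 6, adjusted over the list alone as well (adjusted p = 0.77). Without 1 library, 2 of these passed as higher: cholesterol synthesis without Flox replicate 2 (adjusted p = 0.028) and glycolysis without HepKO replicate 3 (0.036); interferon-stimulated genes passed as lower without Flox replicate 1 (0.0030).

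The list of nuclear oxidative phosphorylation genes was called as lower at the preset correlation (camera adjusted p = 2.64e-06). It did not pass with an estimated correlation (adjusted p = 0.55, correlation 0.66) or with fry (adjusted p = 0.071). Of its 59 members, 7 fell and 52 did not pass, and 6 fell adjusted over the list alone. That share is close to the share of all tested genes called lower, 1397 of 12712. Atp5g1 fell 1.77-fold, Ndufs7 1.67-fold and Sdhd 1.52-fold, while Ndufc1 had 17.8 and 11.2 FPKM in Flox and HepKO livers (adjusted p = 0.10; 0.029 without HepKO replicate 3). Each of these named genes was lowest in HepKO replicate 1. The list median of -0.36 ranged from -0.45 to -0.24 without 1 library. The calls of single genes were fragile. Ndufs7 was lost without any 1 library (adjusted p = 0.052 to 0.077). Atp5g1 and Sdhd were lost without any Flox replicate or HepKO replicate 2 (adjusted p = 0.060 to 0.082 and 0.064 to 0.10). Transcripts of the mitochondrial genome were called as higher (adjusted p = 0.048, and adjusted p = 0.72 with an estimated correlation), although 0 of 13 members rose, 1 fell, and 0 moved adjusted over the list alone. That call was lost without HepKO replicate 1 (adjusted p = 0.43), the library with the high mitochondrial share, and also without Flox replicate 1 (0.13) or Flox replicate 3 (0.097). It was lost as well with a pseudocount of 0.1 (adjusted p = 0.057) and under each of the 3 rescalings (0.065 to 0.072). Mitochondrial dynamics, biogenesis and stress genes had 5 lower and 1 higher of 20 (7 and 1 adjusted over the list alone; adjusted p = 0.016, and adjusted p = 0.33 with an estimated correlation), lost without Flox replicate 1 (adjusted p = 0.058).

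Proteasome subunit genes had 11 lower and 0 higher of 31 (12 and 1 adjusted over the list alone; adjusted p = 4.36e-05, and adjusted p = 0.50 with an estimated correlation). Cytosolic ribosomal protein genes were called as higher with a median of 0.10, or 0.0093 without HepKO replicate 3 (adjusted p = 0.035, and adjusted p = 0.85 with an estimated correlation), with 1 of 39 members higher and 0 adjusted over the list alone. That call was lost without Flox replicate 2 (adjusted p = 0.12), HepKO replicate 2 (0.22) or HepKO replicate 3 (0.30), with a pseudocount of 0.1 (0.051) and after rescaling to a common sum (0.18). Clock genes had 7 higher and 2 lower of 17 (7 and 4 adjusted over the list alone; adjusted p = 0.035, and adjusted p = 0.44 with an estimated correlation), lost without Flox replicate 3 (adjusted p = 0.094) or HepKO replicate 1 (0.057) and under median-ratio rescaling (0.057). Autophagy and mitophagy genes had 2 higher and 6 lower of 25, adjusted over the list alone as well (adjusted p = 0.27). Apoptosis genes had 3 higher and 2 lower of 21 (4 and 2 adjusted over the list alone; adjusted p = 0.69; median -0.02, and -0.14 to 0.089 without 1 library; mean 0.01). Genes of necroptosis, pyroptosis and ferroptosis had 2 higher and 0 lower of 12, adjusted over the list alone as well (adjusted p = 0.51; median 0.03, and -0.014 to 0.087 without 1 library; mean -0.0052).

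The proliferation list did not pass. Of 17 tested cell cycle genes, 1 rose and 2 fell (1 and 3 adjusted over the list alone; adjusted p = 0.47). Pcna, the replication clamp gene, had 23.0 ± 2.11 FPKM in Flox and 24.2 ± 5.14 FPKM in HepKO livers (SD, n = 3; limma adjusted p = 0.83), and the helicase gene Mcm7 had 5.29 ± 0.27 and 4.04 ± 0.14 FPKM (limma adjusted p = 0.053).

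The authors' deposited table lists 4005 genes with p under 0.05 and 2553 with q under 0.05, 1535 of these higher and 1018 lower in HepKO livers. The balance in the main fit here lay the other way, with 1186 higher and 1397 lower, over fewer genes and on another scale. More genes were higher here too after median-ratio rescaling (1434 against 1137) and at a log2 fold change of at least 1 (432 against 264). Fewer were higher after rescaling to a common sum of all genes (1093 against 1417). With a log2 fold change of at least 1 in size as well, the authors' deposited table has 1586 genes, 1031 higher and 555 lower in HepKO livers. Of its 2224 genes with q under 0.05 that were also tested here, 1917 passed in both, all 1917 in the same direction, while 307 passed only in the authors' deposited table and 666 only here. For Nedd4 the authors' deposited table gives a log2 fold change of -1.92 with q = 2.3e-11, and for Vdac1 -0.16 with q = 0.82.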

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

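The 2 rescalings to a common sum were added for lists and named genes after their results were seen; the other alternatives were chosen before the data were examined. The 2583 called genes became 2517 and 2454 with pseudocounts of 0.1 and 0.01, and 0 of them changed direction in any alternative. With no filter on low values 899 genes were lower, and with a mean of at least 5 FPKM 1499 passed (514 higher), both with another number of genes tested. Array weights gave 2174 lower. Requiring a log2 fold change of at least 1 left 696 (432 higher, 264 lower), and adjusted p 0.1 gave 2174 lower. Median-ratio rescaling turned the share of higher calls from 45.9% to 55.8%, while rescaling to a common sum took it to 43.5%, with 14824 genes tested. Leaving out each library in turn gave 1306 to 2282 genes, 685 to 1022 higher and 616 to 1302 lower, with fewer samples. Replicate numbers did not pair the livers (correlations of same-numbered libraries 0.0029, 0.0021 and -0.025); with the replicate block 1551 genes passed, 776 higher and 775 lower, and 30 lists, the female-biased list not passing (adjusted p = 0.052). Of the named genes, 4 did not pass with the block (Atp5g1, Ndufs7, Sdhd and Cyp2d9, adjusted p = 0.057 to 0.092), and Srxn1 passed (0.039). Nedd4 stayed past the threshold and Vdac1 short of it with a pseudocount of 0.1, the rescalings, the replicate block and each library left out. Other settings are not reported for these genes, and Nedd4 (mean 1.47 FPKM) lay under the filter of at least 5 FPKM. Lists called went from 31 to 0 with the correlation estimated per list, and were 28 to 30 without each library; 23 of the 31, and 45 of 53 called named genes, passed without each library in turn. Reversed directions were found only among lists and genes that were not called. Under fry these were antioxidant enzymes (median unchanged at -0.22) and eicosanoid genes (-0.51). Among fits without 1 library they were antioxidant enzymes without Flox replicate 1 (-0.15; range -0.27 to -0.15), cholesterol synthesis without Flox replicate 3 (-0.18; range -0.18 to 0.25), heat shock without HepKO replicate 3 (0.019; range 0.019 to 0.38), stellate markers without Flox replicate 2 or HepKO replicate 1 (-0.16 each; range -0.16 to 0.022), NRF2 targets without Flox replicate 3 (-0.041; range -0.25 to -0.041), endothelial markers without Flox replicate 2 (-0.20; range -0.20 to -0.0080), and Pcna without Flox replicate 2 (-0.012) or HepKO replicate 3 (-0.098; range -0.098 to 0.18). For lists these are medians, and the reversal is of the test's direction. The cause of these changes was not tested. The edgeR and DESeq2 alternatives on counts were not run, since FPKM are not counts. Unknown depth limits what can be said of genes near 0.5 FPKM.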

Other observations

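The tests of library scaling, hour of collection, hepatocyte share, blood and other splits of the libraries were chosen after the results they bear on were seen, while the estimated correlation and the median-ratio rescaling were planned as alternatives; the genes named here beyond the rule were chosen after their values were seen.

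Several lists that were mixed as a whole held opposed members. Among acute phase genes, Saa1 fell from 181 to 57.9 FPKM while Mt1, a metallothionein gene, rose from 582 to 2108 FPKM. Pkm, a pyruvate kinase gene of most non-hepatic tissues, rose from 10.7 to 37.1 FPKM, and Pklr, the liver form, fell from 39.1 to 12.3 FPKM. Of glucose transporters, Slc2a1 rose and Slc2a2, the main hepatocyte form, fell from 18.7 to 6.00 FPKM. Hmox1, the heme oxygenase gene, rose 6.69-fold, and Gclm, a glutathione synthesis gene, fell 2.51-fold. Rrm2, a ribonucleotide reductase gene, rose from 0.531 to 4.92 FPKM, while Ccnd1, which encodes cyclin D, fell from 6.51 to 1.32 FPKM. The platelet gene Pf4 rose 4.03-fold. Of 21 tested snRNA genes, 10 were higher and 1 lower in HepKO livers. Their levels are uncertain, since poly(A) RNA was selected.

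Across all genes, the real split of the 6 libraries called 2583 genes and the highest of the others called 2; 1 of the 10 splits reached the real count, and 10 splits are too few for a share under 0.05.

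The immediate early list was called as higher in HepKO livers (adjusted p = 0.073 with an estimated correlation). Library scaling as the whole cause is argued against: the lowest median log2 fold change of the immediate early list over 3 rescalings was 1.78, against 1.87. A different hour of collection cannot be told apart from genotype: of the 5 called clock genes among those taken for this test, 3 moved as one shift of phase asks (Nr1d1 up 4.31-fold, Per1 and Ciart up) and 2 against it (Hlf down, Nfil3 up). Genotype and tissue handling stay open as untested explanations.

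The 6 lists of complement and coagulation, urea cycle, bile acid, PPARA target, acetaminophen P450 and acetaminophen conjugation genes were called as lower, and neutrophil markers as higher; with an estimated correlation their adjusted p lay between 0.14 and 0.49. The 36 endothelial and stellate markers had a median of -0.088 (quartiles -0.38 and 0.44) and the 13 neutrophil markers 1.81. The permutation p across genes was 2e-05, the smallest the resamples can give. The marker sets were compared after their results were seen and genes are not independent replicates, so this p adds no support. A lower share of hepatocytes alone would raise both marker sets, so by these medians it is argued against as the only cause of both changes. More neutrophils alone would also give this difference, so the comparison cannot tell whether the hepatocyte share fell as well. Alb did not pass, with 25956 FPKM in Flox and 26922 FPKM in HepKO livers. Of the neutrophil markers, 1 is also in another list and 5 have at least 1 FPKM in Flox livers. For all 145 tested members of 6 hepatocyte lists, called or not, the median of -0.60 came no nearer 0 than -0.51 over 3 rescalings. This argues against scaling as the whole cause. More neutrophils, a lower share of hepatocytes and a genotype effect within hepatocytes stay open, and the data may hold several of these.

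Globin transcripts were higher in HepKO livers, with a median log2 fold change of 2.23 over 4 genes that are near-identical in pairs. More blood in the tissue cannot be told apart from other sources: Alas2, the erythroid heme synthesis gene, had a log2 fold change of -0.31 (SE 0.13, adjusted p = 0.14), but its 7.54 FPKM in Flox livers could hide a small contribution. Genotype stays open as an untested explanation.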
